A study of Mus musculus with 4 samples.

How the data were processed

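DNase-seq was carried out on primary T cells from adult male B6CASTF1/J mice, 2 months old per the labels. The 4 libraries were labelled as biological replicates 1 to 4 of a single group. They came from different biosamples but carried the same donor label, so the spread between them may be partly technical, and p-values computed over genes describe these 4 libraries and not other animals. The series held no second group, and no contrast between conditions was made.

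For each library 4 kinds of intervals were used, all on mouse assembly mm10 per the labels. The first 2 were narrowPeak lists called by the authors in each library separately from its own filtered alignments, per the deposited file descriptions. Their signal column, the highest signal within each peak, was used as deposited. Within each library the signal values below 2000 steps were whole multiples of 1 step, within 0.02 of a step in 100% of the 1957 to 1986 distinct values tested, so each library's values carried 1 constant factor. Whether that factor is sequencing depth is not stated in the sources used here, and differences in signal between libraries may hold a difference of scale. The third kind held a p-value type measure per the deposited file descriptions, a false discovery rate (FDR) per stretch of bases for the rate of DNase cuts, and listed stretches with an FDR below 0.05. The last kind held the footprints called by the authors from the alignments and the FDR file, each with the same threshold p-value of 0.01 in the deposited column. Aligner, peak caller, footprint caller and their versions are not given in the sources used here. The plan had named the second interval list hotspots. It turned out to be a larger peak list, in which 98.6% ± 0.196 (SD, n = 4) of the peaks of the smaller list were also found, and it took the place of the hotspots. All peaks of the smaller list contained bases with an FDR below 0.001, and all peaks of the larger list contained bases with an FDR below 0.05. The smaller list was used throughout unless the larger is named.

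Coordinates were compared with GRCm38, no interval ran past the end of its chromosome there, and genes were taken from GENCODE M21. Only chromosomes 1 to 19, X and Y were used. Peaks of the 4 libraries were merged into regions with bedtools 2.31.1, and a region counted for a library when a peak of it overlapped by at least 1 bp. A peak was placed at a promoter when it lay within 500 bp of any annotated transcript start, then in an exon, an intron or between genes, in that order. A gene's promoter signal was the highest signal among its promoter peaks in a library and 0 where it had none. Regions found in all 4 libraries and more than 500 bp from every transcript start were called distal and assigned to the protein-coding gene with the nearest transcript start. Maternal and paternal alleles were not told apart.

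Gene lists, consensus sequences, tests and the rule for named genes were fixed before the data were examined. The 32 lists covered the T cell receptor and CD3 complex, T cell receptor signalling, T lineage transcription factors, naive T cell trafficking and survival, helper T cell factors and cytokines, regulatory T cells, cytotoxic effectors, activation and inhibitory receptors, immature thymocytes, B cells, monocytes and macrophages, neutrophils, natural killer cells, dendritic cells, erythroid cells, hepatocytes, neurons, muscle, endothelium, fibroblasts and stroma, epithelium, Hox cluster A, cytosolic ribosomal proteins, the proteasome, oxidative phosphorylation, class I and class II antigen presentation, the type I interferon response, chemokine receptors, immediate early genes, the cell cycle and testis germ cells. Of their 469 genes, 464 were annotated as protein-coding and tested. Members with a promoter peak in all 4 libraries were counted against all other protein-coding genes with a two-sided Fisher's exact test. The mean number of distal regions per member was compared with 100000 random lists of the same size, matched on decile of the gene's territory (the stretch nearer to its transcript start than to that of another gene), in a two-sided permutation test whose smallest p is 2e-05. Both families of p-values were adjusted over the 32 lists by the Benjamini-Hochberg method, with a threshold of 0.05.

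Named genes were every tested member of the T cell receptor and CD3 list and of the T lineage transcription factor list. From each other list they were up to 4 members with the highest mean promoter signal among those with a promoter peak in all 4 libraries, and up to 2 members, first in the alphabet, with a promoter peak in none. The 15 genes with the most distal regions, the 10 regions with the highest mean rank of signal, and for each library the 5 highest ranking regions missing only there were named too. Other genes named in the text were chosen after their values were seen, and this is said where they appear. Some genes that the rule takes are not reported here.

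Each footprint lying in a peak was padded by 12 bp on each side. Matches to 28 consensus sequences on either strand were counted per kb in these stretches and in the rest of the same library's peaks, and the log2 ratio was averaged over libraries. Ratios for chromosomes and motifs were tested with an exact two-sided sign-flip permutation test over the 4 libraries, in which 2 of the 16 sign assignments are as extreme at best (p = 0.13). Deviations of a library were computed as its log2 signal in a region less its median over the regions found in all 4 libraries, less the mean of the same quantity in the other 3 libraries. Differences of medians carry bootstrap 95% intervals over regions from 2000 draws, and matched comparisons used 10000 draws.

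The alternatives were peaks above each library's median signal, an equal number of top peaks per library, a 50% reciprocal overlap, promoter windows of 100 and 2000 bp, gene-level 5' ends, a promoter peak in at least 1 library, no matching on territory, gene bodies plus 50 kb, no padding of footprints, flanks of 20 to 100 bp as background, distal peaks only, the larger peak list, footprints wholly inside peaks, and leaving out each replicate in turn. Chosen after seeing the data were random lists matched on decile of promoter CpG ratio, starts of protein-coding transcripts only, and peaks placed at random on the same chromosome. On simulated data with known answers the promoter test called 88.2% of changed lists and 1.75% of unchanged ones over 50 simulations of 21938 genes. The distal test called 71.2% and 1.25% over 10 simulations, and a motif planted at a log2 ratio of 2 was recovered at 1.99. The matched comparison of deviations gave a permutation p below 0.05 in 100% of 20 simulations with a planted shift and in 10% of 20 with none. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

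The files give no total read count. If the signal is scaled per 1000000 tags, which the sources used here do not state, the steps correspond to 137, 132, 112 and 170 M tags in replicates 1 to 4. Peak calls are not counts of molecules, so no counting interval was attached to them.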

Results

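DNase-seq maps open chromatin by treating nuclei with DNase I, an endonuclease that cuts DNA most readily where nucleosomes do not cover it, and sequencing the cut ends. It was applied to primary T cells of adult male B6CASTF1/J mice, the first-generation cross of the inbred strains C57BL/6J and CAST/EiJ. The data comprised 4 libraries, labelled as biological replicates of 1 group, so the comparisons were between libraries, between gene groups and between kinds of region. Replicates 1 to 4 held 63569, 64566, 52859 and 63783 peaks of accessible chromatin (mean 61194 ± 5573, SD, n = 4), with a median width of 190 to 200 bp. They held 228527, 232934, 180845 and 232940 footprints (218812 ± 25396, n = 4), which are short stretches inside open chromatin where bound protein shields the DNA from cutting. Read totals were not used here. If the authors' signal is scaled per 1000000 tags, its smallest steps correspond to 137, 132, 112 and 170 M tags in replicates 1 to 4, which would make replicate 3, the library with the fewest peaks, the shallowest. Peak number did not follow this implied depth in the other libraries. Signal below is the authors' peak height, in their own scale for each library, given as mean ± SD over the 4 libraries. A promoter value is the highest at any annotated start of the gene and may belong to a neighbouring gene, as Tap1 and Psmb9 share theirs. Which start gave the value was not examined for single genes.

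In the smaller peak list most merged regions were found in every library. Merging the peaks gave 77390 regions on mm10, of which 45146 (58.3%) held a peak in all 4 libraries, 8791 in 3, 8187 in 2 and 15266 in 1. In the larger peak list 56323 of 114624 merged regions (49.1%) held a peak in all 4. The regions in all 4 were 17311 at promoters, including those of Cd3e, Bcl11b and Lef1, and 27835 distal ones. Of the peaks of replicates 1 to 4, 73.2, 72.1, 87.9 and 73.1% lay in them (76.6% ± 7.55, n = 4), against 0.00165% for peaks placed at random on the same chromosome. The base-pair Jaccard index of the 6 pairs of libraries averaged 0.640, against 0.00252 for random placement. Promoters took 34.7% ± 1.33 of the peaks (n = 4), exons 6.79% ± 0.183, introns 33.0% ± 0.854 and intergenic sequence 25.5% ± 0.352. Replicate 3 alone lacked 5032 regions that the other 3 libraries shared, and 6061 regions were found in replicate 1 alone.

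Signal ranked alike in replicates 2, 3 and 4, and replicate 1 stood apart. Across the 45146 regions, which are not independent replicates, Spearman correlations were 0.971, 0.977 and 0.982 among replicates 2 to 4. Between replicate 1 and the other libraries they were 0.909, 0.888 and 0.888, with 0.968, 0.963 and 0.960 at promoters and 0.830, 0.788 and 0.788 at distal regions. The difference went with the consensus site of CTCF, the zinc finger protein that anchors chromatin loops. At the 5874 distal regions with that site the median signal of replicate 1 lay 0.65 (log2) above the mean of the other libraries, while replicates 2, 3 and 4 deviated by -0.10, -0.23 and -0.25. Replicate 1 lay at -0.22 in the 21961 distal regions without it and at -0.35 in promoters. Its deviation also ran with signal: from the weakest to the strongest of 5 bins of signal in the other libraries it went from 0.85 to 0.33 in distal regions with the site and from 0.11 to -0.76 in those without. In distal regions with RUNX, TCF/LEF, ETS or PU.1 sites it lay at -0.47, -0.45, -0.41 and -0.49. The fall was not particular to these sites. It was -0.56 with the cyclic AMP response element of bZIP factors, -0.41 with AP-1 and -0.39 with forkhead sites. Besides CTCF, the deviation was positive with REST (0.52, 15 regions) and NFAT sites (0.08).

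**Figure D1:**
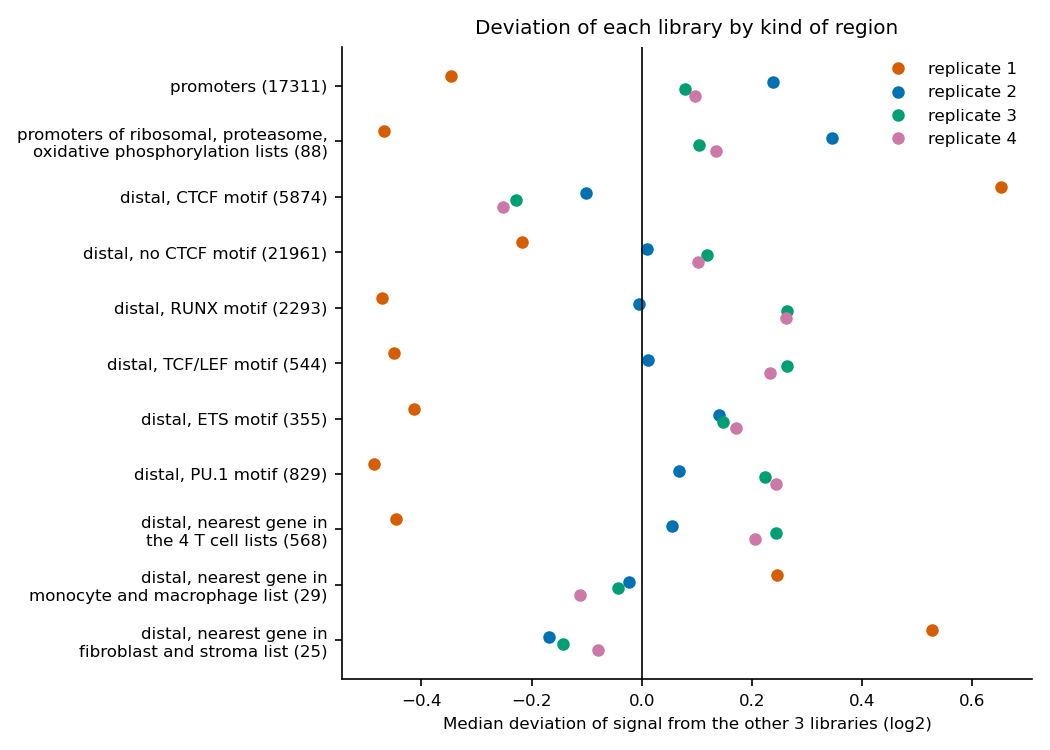
Median deviation of each library's log2 signal from the other 3 libraries, by kind of region found in all 4 libraries; points are libraries, the x axis is in log2 units and the number of regions stands in parentheses. Replicate 1 lies at 0.65 for distal regions with the CTCF site and at -0.45 for distal regions whose nearest gene is in the 4 T cell lists.

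Genes of T cell identity had open promoters. Of the 32 gene lists 10 had more promoters open than other genes and 6 had fewer. Against random lists matched on promoter CpG content these counts were 13 and 3, and with peaks above each library's median signal 10 and 9. All 9 tested genes of the T cell receptor and CD3 list and all 20 T lineage transcription factors carried a promoter peak in all 4 libraries, against 11812 of 21938 protein-coding genes (53.8%). Both lists passed the two-sided Fisher's exact test (adjusted exact p = 0.0124 and 3.59e-05 over the 32 lists). The receptor chain genes Trac, Trbc1 and Trbc2 were in the receptor and CD3 list but are not annotated as protein-coding, and were not tested. The costimulatory receptor gene Cd28 (chromosome 1, 60716800 to 60773359) had a promoter signal of 11.3 ± 4.58 (n = 4). Cd247 (chromosome 1, 165788681 to 165877277), which encodes the zeta chain of the receptor complex, reached 6.33 ± 2.26. The neighbouring genes Cd3g, Cd3d and Cd3e (chromosome 9, 44969572 to 45009627) reached 6.25 ± 2.07, 1.87 ± 0.223 and 5.57 ± 1.82. The surface glycoprotein genes Cd5, Cd2, Cd6 and Thy1 had 4.84 ± 1.52, 3.56 ± 0.817, 3.03 ± 0.827 and 1.81 ± 0.232. The receptor and CD3 list did not pass with only the 5' end of each gene model as its start (adjusted exact p = 0.146) or with starts of protein-coding transcripts only (adjusted exact p = 0.0746).

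Signal at the transcription factor promoters ran from 51.3 to 1.99. Klf2 (chromosome 8, 72319033 to 72321656), which controls T cell quiescence and migration, had the highest value, 51.3 ± 20.5 (n = 4). Ets1 had 24.0 ± 8.71, Tcf3 23.4 ± 9.19, Runx3 20.2 ± 10, Id2 17.1 ± 6.87, Satb1 14.0 ± 6.08, Id3 13.3 ± 3.88 and Bcl11b 12.2 ± 4.40. Foxp1 (8.36 ± 3.04), Tcf12, Runx1, Zbtb7b, Foxo1, Ikzf1, Ikzf3 and Tox (3.56 ± 1.13) lay below Bcl11b. Lef1 had 6.90 ± 2.18, Gata3, needed for the helper lineage, 3.77 ± 1.15, Tcf7, the gene of the T cell factor TCF1, 2.38 ± 0.407, and Myb 1.99 ± 0.520.

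The naive T cell list was open in full. All 12 genes of naive T cell trafficking and survival had a promoter peak in all 4 libraries (adjusted exact p = 0.00244). Among them the lymph node homing receptor gene Ccr7 had 18.3 ± 6.51, the integrin gene Itga4 12.1 ± 3.35 and S1pr1, whose product guides exit from lymph nodes, 9.54 ± 3.77 (n = 4). Of the T cell receptor signalling list 14 of 18 genes were open in all 4 libraries, which missed the threshold (adjusted exact p = 0.100). Among its highest promoters were Grap2 (23.4 ± 12.3), the Src family kinase gene Fyn (19.2 ± 8.53) and the phospholipase gene Plcg1 (12.4 ± 3.89). The 4 exceptions, named after their values were seen, were Ptprc, with a peak in 3 libraries, and Cd4, Lcp2 and Prkcq, with peaks in 2. The list passed with promoter windows of 100 and 2000 bp, with gene-level 5' ends, with peaks above each library's median signal, with a peak in at least 1 library, in the larger peak list and without replicate 2, at adjusted exact p from 0.000489 to 0.0380.

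Lists of helper, cytotoxic, regulatory and activated T cells held both open and closed promoters, and none passed the promoter test. The helper list had 13 of 23 open (adjusted exact p = 0.893), led by Stat3 (26.0 ± 8.09), Bcl6 (11.1 ± 1.70) and Rora (10.9 ± 4.16), and no promoter peak at the cytokine genes Il10 and Il13. The cytotoxic list had 7 of 13 (adjusted exact p = 1), with Prf1, the gene of perforin, at 11.9 ± 4.95, Fasl at 7.96 ± 2.44 and Cd8a at 1.92 ± 0.394, and no peak at Gzmk and Klrg1. The regulatory T cell list had 9 of 11 (adjusted exact p = 0.12), with Ctla4 at 4.17 ± 1.19 and Ikzf2 at 2.65 ± 0.715. Its exceptions were Il10 and, named after its values were seen, Foxp3 with a peak in 2 libraries. Activation and inhibitory receptors had 11 of 14 (adjusted exact p = 0.145), with Tnfrsf9 at 20.8 ± 10.5, Cd69 at 9.62 ± 1.8 and Icos at 9.38 ± 2.96, and no peak at Cd40lg and Havcr2. Immature thymocyte genes had 8 of 14 (adjusted exact p = 1), led by the cell cycle gene Top2a (19.2 ± 3.47). Dntt, the terminal transferase of receptor gene rearrangement, and Notch3 had no peak. Against random lists matched on promoter CpG content, chosen after seeing the data, the signalling, regulatory and activation lists lay above chance (adjusted permutation p = 0.00128, 0.0176 and 0.00288).

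**Figure D2:**
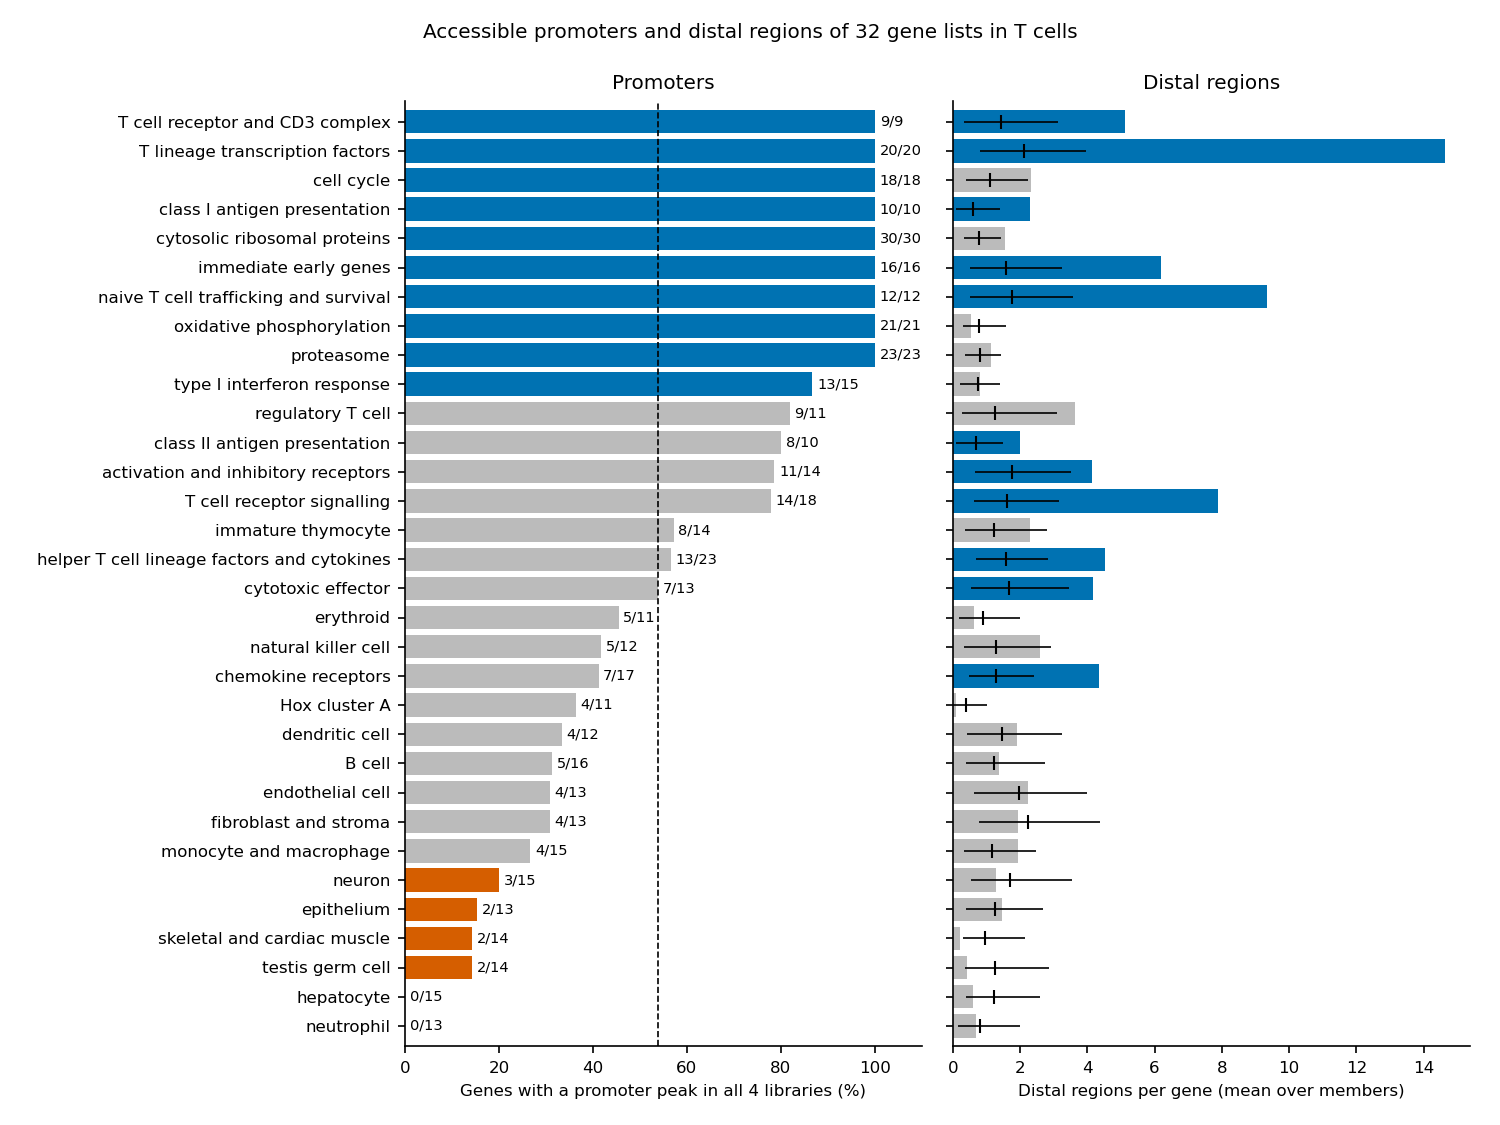
Left, percent of each gene list's tested members with a promoter peak in all 4 libraries, counts beside the bars, dashed line at the 53.8% of all protein-coding genes; right, mean distal regions per member, with black lines for the mean and central 95% of random lists matched on territory. Blue bars lie above and orange bars below at an adjusted p under 0.05, grey bars do not pass, and the T lineage transcription factors reach 20 of 20 promoters and 14.7 distal regions per gene.

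Marker genes of neutrophils and of unrelated tissues were mostly closed. No promoter of the 13 neutrophil or 15 hepatocyte genes had a peak in all 4 libraries (adjusted exact p = 0.000197 and 5.85e-05), and Camp, Cebpe, Alb and Apoa1 had a peak in none. Neuronal genes had 3 of 15 open (adjusted exact p = 0.02), with Tubb3 at 1.83 ± 0.416 and Gad2 at 0.621 ± 0.115. Muscle genes had 2 of 14 (adjusted exact p = 0.0124), Ckm at 3.74 ± 0.98 and Tnni3. Epithelial genes had 2 of 13 (adjusted exact p = 0.02), Cdh1 at 1.70 ± 0.342 and Epcam, and testis germ cell genes 2 of 14 (adjusted exact p = 0.0124), Dazl at 7.66 ± 2.5 and Tnp2. Against random lists matched on CpG content the neuronal and testis lists still lay below chance (adjusted permutation p = 0.0119 and 0.0176), while the neutrophil, hepatocyte, muscle and epithelial lists did not pass (adjusted permutation p = 0.0738, 0.0763, 0.175 and 0.0501). The neuronal list missed the threshold with a 2000 bp window, gene-level 5' ends or the larger peak list (adjusted exact p = 0.13, 0.0609 and 0.0569), and the epithelial list with a 2000 bp window, a peak in at least 1 library or without replicate 3 (adjusted exact p = 0.141, 0.243 and 0.0501).

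Lists of blood cells other than T cells and neutrophils, and of endothelium and fibroblasts, did not pass in either direction. B cell genes had 5 of 16 promoters open (adjusted exact p = 0.130), namely Pou2af1 at 12.8 ± 5.42, Pax5 at 2.94 ± 0.536, Ebf1 at 1.94 ± 0.419, Cr2 and, named after its values were seen, Cd22. Monocyte and macrophage genes had 4 of 15 (adjusted exact p = 0.0748), with Cebpb at 2.85 ± 0.720 and the lysozyme gene Lyz2 at 0.781 ± 0.192, and no peak at Adgre1 and C1qa. Natural killer genes had 5 of 12 (adjusted exact p = 0.645), with Il2rb at 9.77 ± 4.43, and this list shares genes with the T cell lists. Dendritic cell genes had 4 of 12 (adjusted exact p = 0.315), with Tcf4 at 9.77 ± 2.91 and Irf8 at 7.45 ± 2.34. Erythroid genes had 5 of 11 (adjusted exact p = 0.843), with the transferrin receptor gene Tfrc at 28.7 ± 13.1 and no peak at the globin gene Hba-a1. Endothelial genes had 4 of 13, with Pecam1 at 6.35 ± 2.09, and fibroblast genes 4 of 13, with Vim at 4.68 ± 1.32, Col1a1 at 4.23 ± 1.08 and the T cell marker Thy1 (adjusted exact p = 0.145 for both). In Hox cluster A 4 of 11 promoters were open, Hoxa7 the highest at 5.27 ± 1.59 (adjusted exact p = 0.433). That list lay below random lists matched on CpG content (adjusted permutation p = 0.0119). With gene-level 5' ends the B cell, endothelial and fibroblast lists lay below chance (adjusted exact p = 0.0417 for each), with a 100 bp window the fibroblast list did (0.04), and with peaks above each library's median signal the monocyte, erythroid and endothelial lists did (0.0185, 0.0257 and 0.0442).

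Housekeeping and inducible gene groups were open in full. Every member of the cytosolic ribosomal protein (30 of 30), proteasome (23 of 23), oxidative phosphorylation (21 of 21), cell cycle (18 of 18) and immediate early (16 of 16) lists had a promoter peak in all 4 libraries. Adjusted exact p was 3.66e-07, 1.87e-05, 3.59e-05, 8.15e-05 and 0.000216. Rpl27 and Rpl3 had 34.1 ± 17.9 and 33.2 ± 11.2 (n = 4), the proteasome subunit gene Psma2 39.6 ± 17.4 and the complex I subunit gene Ndufb5 29.4 ± 13.0. The replication genes Mcm5 and Pcna had 30.3 ± 12.8 and 28.8 ± 12.8, and the cyclin gene Ccne1 36.3 ± 8.33. The transcription factor genes Jund, Jun and Nr4a1, which respond within minutes to stimulation, had 42.4 ± 17.2, 41.2 ± 14.2 and 32.8 ± 13.1. Against random lists matched on CpG content the cell cycle list missed the threshold (adjusted permutation p = 0.0501).

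Antigen presentation and interferon genes were largely open as well. All 10 class I genes passed (adjusted exact p = 0.00794), with the heavy chain genes H2-D1 at 57.4 ± 24.9 and H2-K1 at 31.7 ± 14.5 (n = 4). The peptide transporter gene Tap1 (chromosome 17, 34187553 to 34197225) had 28.7 ± 9.75, a value shared with its neighbour Psmb9. Class II genes had 8 of 10 (adjusted exact p = 0.160), with H2-DMa at 36.3 ± 14.7 and H2-Aa at 8.24 ± 2.22. Ciita, the master regulator of class II transcription, and H2-DMb1 had no peak in any library. The list lay above random lists matched on CpG content (adjusted permutation p = 0.00128). The type I interferon list had 13 of 15 (adjusted exact p = 0.0330), with Irf9 at 22.5 ± 7.45 and Irf7 at 10.6 ± 2.76, and none at Ifit3 and Oas1a. It did not pass with a 2000 bp window, with peaks above each library's median signal or with a peak in at least 1 library (adjusted exact p = 0.0621, 0.106 and 0.0625). Chemokine receptor genes had 7 of 17 (adjusted exact p = 0.414), with Cxcr4 at 15.8 ± 4.31 after Ccr7 and no peak at Ccr1 and Ccr10.

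Distal open regions gathered around T cell genes, and 11 of the 32 lists had more of them than chance. The T lineage transcription factors had 14.7 distal regions per gene against 2.10 in random lists matched on territory, the naive T cell list 9.33 against 1.75 and the T cell receptor signalling list 7.89 against 1.59. Each of these had permutation p = 2e-05, the smallest the draws can give, and adjusted p = 0.00016. Among the T lineage transcription factors Foxp1 had 36 distal regions, Ets1 30, Satb1 23, Lef1 and Foxo1 22 each, Bcl11b and Runx1 19 each, and Gata3 and Tcf7 14 each. At the low end Klf2 and Id3 had 3 each and Tcf3 and Zbtb7b 2 each. Bach2, a repressor that keeps T cells naive, also had 36, but it is not in that list and was named for this number. The immediate early list had 6.19 against 1.57 (adjusted permutation p = 0.00016), the T cell receptor and CD3 complex 5.11 against 1.43 (0.00192), chemokine receptors 4.35 against 1.27 (0.000768) and helper genes 4.52 against 1.58 (0.000853). Class I genes had 2.3 against 0.600 (adjusted permutation p = 0.0036) and class II genes 2 against 0.694 (0.0196). Cytotoxic genes had 4.15 against 1.66 (adjusted permutation p = 0.0435) and activation genes 4.14 against 1.76 (0.0402). Without matching on territory the class I and class II lists did not pass (adjusted permutation p = 0.346 and 0.448). With peaks above each library's median signal the cytotoxic and activation lists did not pass (adjusted permutation p = 0.0817 and 0.133), nor did the cytotoxic list without replicate 2 (0.0527) or the activation list without replicate 3 (0.0886). At the 568 distal regions nearest to genes of the receptor and CD3, signalling, transcription factor and naive T cell lists, the median signal of replicate 1 deviated by -0.45 (log2) from the other libraries and that of replicates 2 to 4 by 0.06, 0.24 and 0.21.

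No list had fewer distal regions than chance at the threshold. Muscle genes had 0.214 per gene against 0.965 (adjusted permutation p = 0.0731), testis genes 0.429 against 1.26 (0.223), hepatocyte genes 0.600 against 1.22 (0.402) and Hox cluster A 0.0909 against 0.386 (0.432). Erythroid, neuronal, neutrophil and fibroblast genes had 0.636, 1.27, 0.692 and 1.92 against 0.880, 1.69, 0.8 and 2.24 (adjusted permutation p = 0.812 to 1). Regulatory T cell genes had 3.64 against 1.26 (adjusted permutation p = 0.0604), ribosomal protein genes 1.53 against 0.767 (0.0728) and cell cycle genes 2.33 against 1.1 (0.0784). Natural killer, thymocyte and monocyte genes had 2.58, 2.29 and 1.93 against 1.29, 1.23 and 1.17 (adjusted permutation p = 0.2, 0.244 and 0.313), and proteasome and dendritic cell genes 1.13 and 1.92 against 0.804 and 1.46 (0.430 and 0.661). For oxidative phosphorylation, interferon, epithelial, endothelial and B cell genes adjusted permutation p lay between 0.712 and 0.878. With regions inside the gene body plus 50 kb the regulatory T cell list lay above chance (adjusted permutation p = 0.0355) and Hox cluster A below it (0.00784), the latter also without matching on territory (0.0428).

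Among single genes Tgfbr2 (chromosome 9, 116084293 to 116175360), which encodes a receptor for TGF-beta, had the most distal regions, 39, with a promoter signal of 11.5 ± 3.95 (n = 4). After Bach2 (promoter 22.2 ± 9.36) and Foxp1 came 3110018I06Rik and Pced1b with 31 each, then Ets1 and the protein kinase C gene Prkcq with 30 each and Wwox with 29. Bcor, Pde4d and Smad7 had 28 each, and Chd7 and Cog6 27 each. 3110018I06Rik (chromosome 12, 107488632 to 107489636) had no promoter peak in any library, and its next protein-coding neighbour toward higher coordinates is Bcl11b (107910403 to 108003602). Tnfaip3, an inhibitor of NF-kB signalling, had 25 distal regions and a promoter signal of 39.6 ± 14.1. The ubiquitin ligase gene Cblb, a restraint on T cell activation, had 24 and 23.3 ± 10.2.

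The X chromosome carried fewer peaks per megabase than the autosomes, and the Y chromosome very few. Autosomes held 24.9 ± 2.27 peaks per Mb, the X 9.55 ± 0.858 and the Y 0.409 ± 0.0564 (n = 4). The log2 ratio to autosomes was -1.38 ± 0.0534 for the X and -5.93 ± 0.0983 for the Y, negative in 4 of 4 libraries. The exact two-sided sign-flip permutation p of 0.13 for each is the smallest that 4 libraries allow. The mice were male, so the X and Y, unlike the autosomes, were not present in pairs. Peaks per Mb were taken over all bases of known sequence, including repeats where reads may not be placed. What copy number and repeats add to these ratios was not tested. The 17 regions of the Y chromosome open in all 4 libraries included the promoters of 4 widely expressed genes, named after their values were seen, Kdm5d (2.57 ± 0.850), Eif2s3y (5.65 ± 1.56), Uty (6.18 ± 2.57) and Ddx3y (7.49 ± 2.94).

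Footprints lay mostly inside peaks, and sites of NRF1, ZBTB33 and CTCF had the highest ratios of footprints to the rest of the peaks. Of the footprints of replicates 1 to 4, 77.2, 74.6, 77.1 and 74.4% overlapped a peak (75.8% ± 1.56, n = 4). Relative to the rest of the same peaks, padded footprints were enriched by a log2 ratio of 6.36 ± 0.344 for sites of NRF1, an activator of mitochondrial genes. ZBTB33 sites reached 4.72 ± 0.343, CTCF 4.01 ± 0.377, ZNF143 3.97 ± 0.265 and the cyclic AMP response element of bZIP factors 3.60 ± 0.0586 (n = 4). NRF1, ZBTB33, ZNF143 and REST sites were rare, with 4 to 9 matches per library in the rest of the peaks. CTCF sites occurred 1.37 times per kb of footprint and 0.0869 times per kb of the rest. RFX (2.97 ± 0.314), the neuronal repressor REST (2.86 ± 0.338), ETS (2.62 ± 0.331), SP/KLF (2.48 ± 0.0904), YY1 (1.35 ± 0.0808) and NFY (0.96 ± 0.0261) followed. Ratios below these were found for sites of TCF/LEF (0.59 ± 0.191), RUNX (0.58 ± 0.101), NF-kB (0.58 ± 0.0592), KLF (0.52 ± 0.105), IRF (0.40 ± 0.118), PU.1 (0.18 ± 0.0518) and ZEB (0.11 ± 0.0388).

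Of the 28 consensus sequences 18 were enriched in footprints in all 4 libraries and 6 were depleted in all 4. Each of these has an exact two-sided sign-flip permutation p of 0.13, the smallest that 4 libraries allow. The depleted ones were NFAT (-0.13 ± 0.0128), the E2A/HEB E-box (-0.19 ± 0.0408), AP-1 (-0.35 ± 0.0349), the MYOD E-box (-0.45 ± 0.0646), forkhead (-0.58 ± 0.0709) and GATA (-0.69 ± 0.0324). HNF4 (0.26 ± 0.305), POU/OCT (0.12 ± 0.0992) and MEF2 (-0.02 ± 0.237) did not have 1 sign in all libraries, and HNF1 had too few matches for a ratio. Padded footprints had a GC content of 57.5 to 58.8% in the 4 libraries and the rest of the peaks 53.7 to 54.0%. Consensus sequences were also counted in reverse order, as a check on base content. Reversal turns CpG pairs into GpC and GpC into CpG, so it is no check on CpG content. The reversed NRF1, RFX, REST and YY1 sequences gave no ratio, and SP/KLF reads the same in reverse. For these sites the check says nothing. AP-1, forkhead and ZEB gave -0.35, -0.56 and 0.13 in reverse, close to their own values. TCF/LEF, NF-kB, KLF and IRF kept part of theirs (0.35, 0.29, 0.20 and 0.12). CTCF, ETS, RUNX and NFY gave 0.26, 0.02, -0.32 and -0.07. NFAT, E2A/HEB, MYOD and GATA gave -0.46, 1.04, -0.10 and -0.32. PU.1 and POU/OCT turned negative without padding (-0.23 and -0.47), POU/OCT also in distal peaks (-0.16), and the E2A/HEB E-box turned positive against flanks of 20 to 100 bp (0.05). NFAT was at 0.00 in distal peaks, and AP-1 at -0.02 against flanks.

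**Figure D3:**
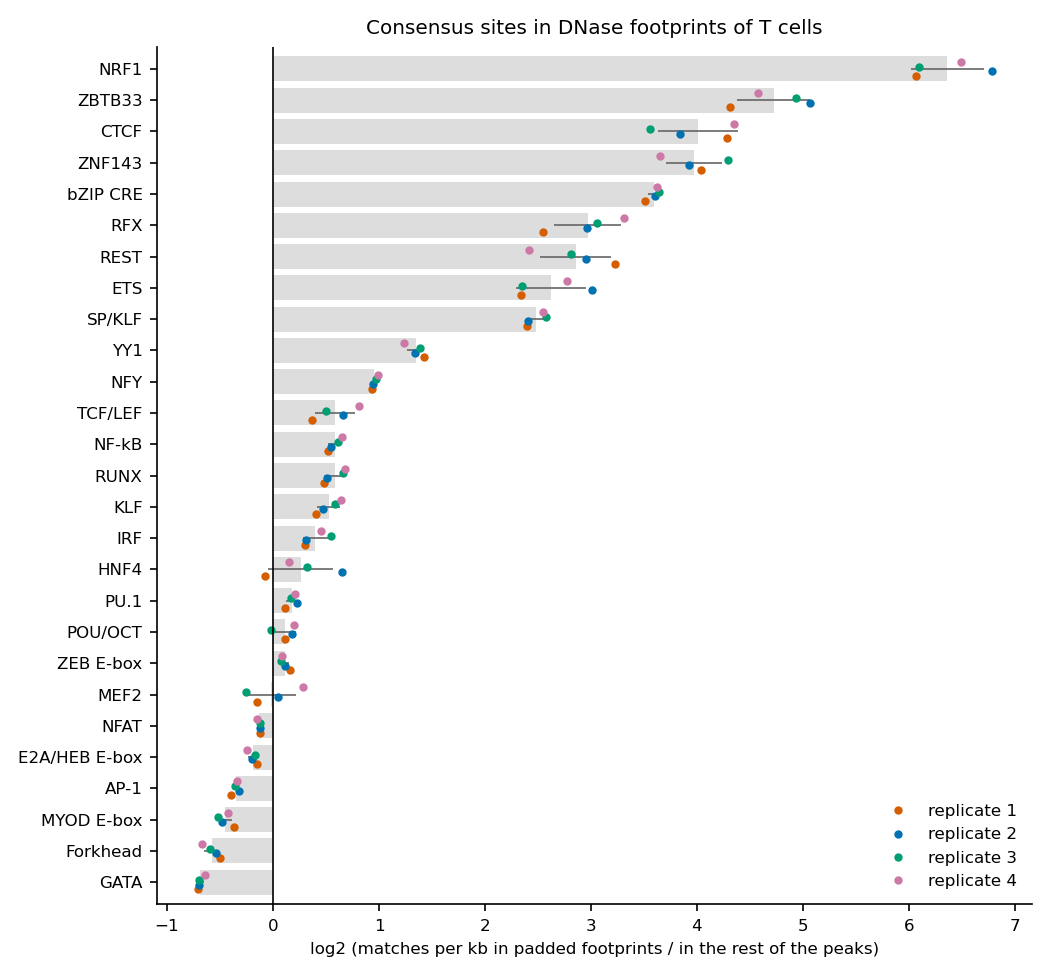
Log2 ratio of consensus matches per kb in padded footprints to matches per kb in the rest of the same library's peaks (x axis), with means as bars, SD as lines and the 4 libraries as points. NRF1, ZBTB33, CTCF and ZNF143 lie highest and GATA and forkhead sites lowest.

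The strongest regions open in all 4 libraries lay at a ribosomal RNA gene, at promoters and at the end of the X chromosome. The highest was on chromosome 17, 39846781 to 39846920, inside CT010467.1, a gene annotated as ribosomal RNA, with a signal of 143 ± 46.3 (n = 4). Also among the 10 highest ranks were the promoter of Dynlt1b (chromosome 17, 6429981 to 6430180; 83.9 ± 27.5) and an exon of Lars2 (chromosome 9, 123461881 to 123462140; 87.0 ± 29.4). The promoters of Mplkip (69.0 ± 29.6), Esrra (71.1 ± 32.5) and Eif5a (65.9 ± 28.2) were in the same group. The other 4 lay at the far end of the X chromosome, between 169991141 and 170010160, in introns of Mid1 and at the start of Gm21887, with 81.3 to 84.8. Of the 36-base sequences in the strong regions of that end, 89.5% occurred more than once in the reference, with copies on the Y chromosome. Replicate 1 had the highest signal at the ribosomal RNA gene (206, against 150, 110 and 105) and the Lars2 exon (119, against 104, 59.0 and 65.6). It had the lowest at the rest of the 10. Copies of sequence were counted only for the X end, so signal added by repeats at the other regions was not tested.

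Strong regions missing in a single library lay next to peaks of that library. The highest ranking were the promoters of Ppp1r10 (24.6 ± 8.37 in the 3 other libraries) and Upf2 (22.3 ± 6.68) in replicate 1 and of Rela (6.28 ± 0.469), which encodes an NF-kB subunit, in replicate 2. In replicate 3 they were the clock gene Cry1 (18.5 ± 6.44) and Mynn (14.6 ± 6.73), and in replicate 4 Ascc1 (11.0 ± 3.44) and Zbtb20 (8.79 ± 3.30). At each of the 20 regions named by rank the library without the region had a peak of its own 0 to 380 bp away. Each of the 20 also held bases with an FDR below 0.001 in that library. These regions were thus not closed there, and only the peak call was missing. Replicates 1 to 4 each lacked 2264, 834, 5032 and 661 regions that the other 3 libraries shared, and 69.2, 62.5, 70.7 and 72.5% of these were in the larger peak list of the same library.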

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

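The tests of dilution by other cells and of extra sequence copies at the end of the X chromosome were chosen only after the results were seen. In a screen for a single library far from the other 3, 15 of 164 sets of values stood out, 6 for replicate 1, 2 for replicate 2, 7 for replicate 3 and 0 for replicate 4. Chance alone gives about 1 in 20, here 8.2, and many of these sets rest on the same peaks. The series holds 1 group, so the explanations tested below had no contrast between conditions to rest on.

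Replicate 1 had the highest median deviation in distal regions with the CTCF site (0.65, log2) and the lowest in those with the ETS site (-0.41, against 0.14, 0.15 and 0.17). Distal regions with the CTCF site minus those without it gave 0.87 in replicate 1 and -0.11, -0.35 and -0.35 in replicates 2 to 4, and 17.1% of the regions found in replicate 1 alone had the site, against 6.08, 0.612 and 2.69% of those found in replicate 2, 3 or 4 alone. The site lay in 14.7% of regions found in all 4 libraries and 21.1% of the distal ones. The share in replicate 1 was thus near that of shared regions, and the others lay below it. The tables argue against GC content and against a compressed signal range as the whole cause, since the difference was at least 0.75 in each of 5 bins of GC content and at least 0.74 in each of 5 bins of signal. T cells diluted by other cells cannot be told apart from the pattern: 88 promoters that all cells use lay at -1.12 from the CTCF regions (95% bootstrap interval -1.21 to -1.04), but matched on signal at -0.35 (-0.45 to -0.17), an interval that reaches above the bound of -0.2 set for excluding dilution. A difference in DNase digestion or in the DNA fragments kept for sequencing could also raise CTCF regions in 1 library, and it was not tested.

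Distal regions near T cell genes were lower in replicate 1, with a median deviation of -0.45 over 568 regions of 4 T cell lists. Most of this may be the general fall of regions without the CTCF site: the 520 T cell regions without it lay at -0.50 and others matched on signal at -0.34, a difference of -0.16 that is within the bound of 0.2 set for this explanation. The same matched difference was 0.007, 0.16 and 0.11 in replicates 2, 3 and 4. A remainder may stay, as permutation of the matched regions gave p = 1e-04 (two-sided) in replicate 1, the smallest it can give. The test gave the same p in replicates 3 and 4, but for differences of the opposite sign. Each deviation is taken from the mean of the other libraries, so a fall in replicate 1 by itself raises the others. Their p-values are therefore not separate evidence for or against replicate 1 standing apart. The permuted units are regions, which are not independent replicates. In simulated data with no shift the same test gave p below 0.05 in 10% of 20 simulations. Other immune cells in replicate 1 cannot be told apart from this: 0% of 67 B cell, monocyte, neutrophil, dendritic and erythroid genes had a promoter peak there alone, but 18 of them were open in all 4 libraries and could not gain one, and the 0.419% of all genes with a peak in replicate 1 alone would give 0.281, so the bound of 10% set for this test was too high to decide. The 29 distal regions near monocyte genes lay at 0.25 in replicate 1 (0.53 in the 7 with the CTCF site, 0.18 in the 22 without). All distal regions without the site lay at -0.22. The 22 regions near B cell genes lay at 0.13 and the 23 near dendritic cell genes at 0.04 in replicate 1. No test was run on these few regions.

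The last 2 Mb of the X chromosome, where Mid1 spans the boundary of the region shared with the Y chromosome in C57BL/6 mice, held 29 regions open in all 4 libraries, with a median signal 3.42, 2.71, 3.14 and 3.27 times that of the 1069 other X regions in replicates 1 to 4. Reads shared between copies of the sequence may contribute, since 89.5% of the 2858 words of 36 bases in its 14 strong regions occurred more than once in the reference. The same 89.5% had a copy on the Y chromosome. In the larger list no peak of any library lay past base 90744820 of the 91744698 bases of the Y. Further copies in these animals, counted at 1 place of the reference, were taken to give a ratio of at least 4 in each library and to be excluded by one under 2. These bounds were assumed after the values were seen, and copy number was not measured. The lowest ratio, 2.71, lay between these bounds. Sequence shared with the Y chromosome in these males, further copies and stronger opening of this end cannot be told apart.

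The mean Spearman correlation of replicate 1 with the other libraries was the lowest over all regions (0.895), at promoters (0.964) and at distal regions (0.802). Replicate 3 had the fewest peaks (52859), the fewest in the larger list (70483, against 85662, 85159 and 86012) and the fewest footprints (180845). Its peaks lay most often in regions of all 4 libraries (87.9%), its footprints most often overlapped footprints of all 4 (53.4%, against 42.1, 40.2 and 40.8%), and its intergenic share was lowest (24.99%, against 25.7, 25.7 and 25.6%). Replicate 2 had the highest promoter signal at Plcg1 (18.2, against 9.99, 10.2 and 11.3) and at Cxcr4 (22.3, against 13.4, 13.4 and 14.2). Its median deviation over the 17311 promoter regions was 0.24 (log2), against -0.35, 0.08 and 0.10. Being highest at promoters was thus not particular to these genes. Replicate 3 had the lowest promoter signal at Pax5 (2.14, against 3.28, 3.21 and 3.13). The 25 distal regions near fibroblast and stroma genes lay at 0.53 in replicate 1 (0.91 in the 7 with the CTCF site, -0.29 in the 18 without), against -0.17, -0.14 and -0.08 in the other libraries. In the stretches with an FDR below 0.001, a measure the comparisons did not use, 47.9% ± 1.42 of the length lay outside the peaks (n = 4).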

How the results depend on the processing

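Random placement of peaks, matching on CpG content and starts of protein-coding transcripts were tests chosen after the results were seen. No paired analysis was possible because the series holds 1 group.

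Using only peaks above each library's median signal gave by construction fewer peaks (30597), a promoter share of 46.6% and log2 ratios to autosomes of -1.76 for the X and -6.65 for the Y chromosome. The larger peak list gave -1.30 and -5.36, a Jaccard index of 0.590 and 83.4% of footprints in peaks, and distal peaks alone gave -1.50 and -5.63. A reciprocal overlap of 50%, stricter by construction, lowered the share of shared peaks to 65.1% and the Jaccard index to 0.578, and random placement gave 0.00165% and 0.00252. Promoter windows of 100 and 2000 bp gave shares of 24.6 and 48.6%, gene-level 5' ends 26.6%, and 71.0% of footprints lay wholly inside a peak. Matched on CpG content 3 lists lay below chance in the promoter test, and 1 list did in the distal test without matching on territory and 1 with gene bodies plus 50 kb, Hox cluster A in both. Signs reversed for PU.1 (-0.23) and POU/OCT (-0.47) without padding, for the E2A/HEB E-box against flanks (0.0544) and for POU/OCT in distal peaks (-0.16), where NFAT lay at 0 (0.000378). Except where the construction is named, the cause was not tested.

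Leaving out 1 replicate at a time gave 60070 to 63973 peaks, 80435 to 85611 in the larger list and 214102 to 231467 footprints. It gave a Jaccard index of 0.620 to 0.668 and 78.7 to 81.1% of peaks shared by all remaining libraries, by construction a looser rule than all 4. It gave promoter shares of 34.0 to 35.0%, footprint shares of 75.3 to 76.3%, and ratios of -1.40 to -1.36 for the X and -5.97 to -5.90 for the Y. In the promoter test 10 to 11 lists lay above and 5 to 6 below, in the distal test 10 to 11 above and 0 below, and 18 to 19 motifs were enriched and 6 depleted. Over single lists and alternatives, left-out replicates included, the promoter test kept its side of the threshold in 349 cases, gained a call in 19 and lost one in 16, the distal test in 215, 3 and 6. Likewise 125 motif values moved by less than 1 SD and 57 by more without a change of sign. Leaving out 1 library cannot move a mean over 4 by 1 SD, so all 27 motif values stayed within it in each such setting. With flanks as background, distal peaks only and no padding, 7, 7 and 3 values stayed within 1 SD. In these settings 19, 16 and 22 moved by more without a change of sign, and 1, 2 and 2 changed sign. What depth limits was not tested: the implied depth rests on an unstated scale, and replicate 3 had the lowest (112 M tags) and the fewest peaks, while replicate 4 (170 M tags) had fewer peaks than replicate 2 (132 M tags). HNF1 gave no value, with too few matches.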

Other observations

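The tests of gene families, antigen receptor loci and dense stretches below were all chosen after seeing the data, and are given as values. Among the antigen receptor loci the alpha and delta, beta and heavy chain loci held more regions per Mb than the gamma, kappa and lambda loci. The alpha and delta locus (chromosome 14, 52427928 to 54224206) held 55 regions open in all 4 libraries, or 30.6 per Mb, and the beta locus (chromosome 6, 40891229 to 41558452) 19, or 28.5 per Mb. The gamma locus (chromosome 13, 19178024 to 19352756) held 1, or 5.72 per Mb. The immunoglobulin kappa locus (chromosome 6, 67555497 to 70726966) held 2 regions, or 0.631 per Mb, and the lambda locus (chromosome 16, 19061618 to 19260859) 0. The heavy chain locus (chromosome 12, 113254830 to 116010093) held 68, or 24.7 per Mb. Annotated transcript starts held 42 of these, 34 of those in the alpha and delta locus and 13 of those in the beta locus. Downstream of the constant gene Trac an intergenic region (chromosome 14, 54227421 to 54227720) had a signal of 40.3 ± 17.2 (SD, n = 4), and downstream of Trbc2 another (chromosome 6, 41554381 to 41554620) had 18.3 ± 7.83.

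Gene families defined by the start of their symbol differed widely in the share of promoters open in all 4 libraries. All 8 Gimap genes, GTPases of lymphocyte survival, all 49 Mrpl genes of the mitochondrial ribosome, 56 of 67 Hist genes, 51 of 55 Eif genes and 313 of 397 Zfp genes were open. Of the olfactory receptor genes (Olfr) 5 of 1135 were, of the vomeronasal receptor genes (Vmn) 1 of 331, of the keratin genes (Krt) 5 of 113, of the Cyp genes 14 of 107 and of the protocadherin genes (Pcdh) 8 of 69. The Klra genes, receptors of natural killer cells, had 0 of 11 and the beta-defensin genes (Defb) 0 of 42. Among stretches of 100 kb the most distal regions, 22, lay on chromosome 5 from 124000001, with Vps37b, Abcb9 and Hip1r. The next 3, with 17 each, lay on chromosome 13 from 23400001, with Abt1, Btn1a1 and Btn2a2, on chromosome 14 from 122000001, with Timm8a2 and Tm9sf2, and on the X chromosome from 12000001, with Bcor. Chromosome 11 had the most regions open in all 4 libraries per Mb (31.8) and chromosome 14 the fewest among autosomes (13.0). Of the regions missing in replicate 1, 2, 3 or 4 alone, 87.7, 85.7, 82.5 and 95.6% held bases with an FDR below 0.05 in that library, and 29.7, 34.5, 20.9 and 38.6% held bases below 0.001.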
